A study of Mus musculus with 8 samples.

How the data were processed

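Chromatin accessibility was measured by ATAC-seq in 8 libraries of the mouse breast cancer line PB3, 2 for each of 4 lines: the untreated parental line (PB3-Parental) and derivatives resistant to eribulin (PB3-ERI-R), paclitaxel (PB3-PAC-R) and vinorelbine (PB3-VIN-R). Samples were grouped by the line that the labels give. The submitters' processing notes name bcl2fastq 2.20.0.422, cutadapt 1.9.1, Bowtie2 2.2.6, Picard, MACS2 2.1.1, featureCounts and deepTools, with the builds mm10 and GRCm38. The settings of these tools, and whether reads or fragments were counted, are not given in the sources used here.

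The deposited table holds raw counts per consensus region and library, as whole numbers with no normalization. The deposited peak lists, 1 per line, give a peak score in the narrowPeak format that ran from 830 to 1000, the range of a scaled reproducibility score at a threshold of 0.01. The deposited peak lists also give a fold enrichment at each summit, a ratio over the local background. The deposited peak lists further give a -log10 q value (neg_log10_p) for each summit. The deposited list of consensus regions holds other values, namely the 0-based start and end of each region. Each of the 57417 consensus regions was identical to an interval of the merged union of the 4 peak lists, so a region is a place where at least 1 line had a peak. Region widths ran from 73 to 2316 bp with a median of 473.0 bp.

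Counts over the consensus regions totalled 10521964 to 24052237 per library. A floor of 3 counts corresponds to 0.125 to 0.285 CPM (counts scaled by library size) in a single library. For a line with no counts, the floor was 3 counts over its 2 libraries. Intervals and floors cover counting error only, since the counts carry no molecular identifiers. Replicate libraries differed by more than counting error: chi-square per degree of freedom ran from 5.06 for PB3-ERI-R to 10.57 for PB3-VIN-R.

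Regions were tested with edgeR 4.0.16 (R 4.3.3): filterByExpr by line, TMM normalization, and a quasi-likelihood fit of all 8 libraries with 1 term per line. TMM factors were 0.8023 and 0.8584 for PB3-ERI-R and 1.036 to 1.09 for the other lines. The filter kept 57415 regions. The residual degrees of freedom were 4, the prior degrees of freedom 9.9, and the common biological coefficient of variation 0.161. A region was called changed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were the fold change divided by the square root of its F statistic. CPM values use library sizes after TMM.

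Regions were assigned to the nearest of 21887 protein-coding genes of the RefSeq annotation of GRCm38.p6, inside the gene or at most 50 kb from it, which placed 48280 regions. The annotation table used here has no strand, so distances were taken to the gene body, not to a transcription start, and a region within 1 kb of either gene end stood in for a promoter. Counts were summed over the regions of each gene to give 14939 tested gene loci, fitted in the same way (coefficient of variation 0.112, prior degrees of freedom 6.3). A locus value is thus the summed accessibility in and near a gene and not its expression.

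The 20 gene lists, with 467 entries for 455 genes (452 in the annotation), were fixed before the data were examined, as were the tests, the comparisons, most of the alternative settings and the rule for named genes. They cover epithelial adhesion and keratin genes, epithelial transcription and splicing factors, EMT (epithelial-mesenchymal transition) transcription factors, mesenchymal and extracellular matrix genes, the TGF-beta pathway, tubulins and microtubule-associated proteins, drug efflux and detoxification, the SWI/SNF complex, interferon response, mitotic cell cycle, apoptosis regulators and the AP-1 family. They also cover mammary basal and mammary luminal markers, markers of macrophages, T and B cells, endothelium, adipocytes and neural cells, and housekeeping genes. Lists were tested against all other loci with camera (limma 3.58.1) at a preset correlation of 0.01, and with a correlation estimated for each list, adjusted over the lists and the 3 comparisons against the parental line. Fry, which asks whether the loci of a list move one way on balance, was run beside it. Single loci of the T and B cell list in PB3-ERI-R are not reported here.

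The rule named, for each comparison against the parental line, the 5 gained and 5 lost regions with the largest change among those past the threshold with an average log2 CPM of at least 2, the same sign in all pairings of replicates and a gene within 50 kb, 1 region per gene. Between resistant lines it named 3 and 3. From each list it named up to 3 loci with the smallest adjusted p. Cdh1, Epcam, Zeb1, Vim, Abcb1a and Abcb1b were named whatever their values.

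Overlap of peak lists was computed with bedtools 2.31.1 and given with 95% exact binomial intervals (scipy 1.17.1). Shares of regions near a gene end were compared with two-sided Fisher's exact tests (R 4.3.3) against tested regions that were not called, adjusted over the comparisons. These intervals and tests treat peaks or regions as independent, which they are not, so they describe only these peaks and regions. Agreement between resistant lines was the Pearson correlation and covariance of log2 fold changes across regions, which are not independent replicates. It was set against 20 simulations of unchanged lines compared with the same 2 parental libraries. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

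The pipeline was tested on simulated data with known changes. At the region level it recovered 98 and 100% of changes of -2 and 2 on the log2 scale, and 36 and 52% of changes of -1 and 1, with 8 false calls among 57417 regions. At the locus level it recovered 90 to 100%, with 8 false calls. Only 50 regions or loci were changed at each size, so these simulations do not test a difference that covers most regions, as in PB3-ERI-R.

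Alternatives were DESeq2 size factors, no scaling factor, loess offsets on abundance, no filter, a mean CPM of at least 2, copy number offsets (the median log2 ratio in 5 Mb windows holding at least 15 regions or loci, and of the chromosome elsewhere), the DESeq2 1.42.0 Wald test, a fit of only the compared lines, a replicate block, leaving out each library, stricter thresholds and other gene windows. Thinning to 10521964 counts per library, leaving PB3-ERI-R out of the fit, and doing so with a replicate block were added after seeing the data. No genome sequence was used here, so the planned tests of 28 sequence motifs and the corrections for GC content were not run. With 2 libraries per line, no test of outlying samples or of other splits of the samples was made.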

Results

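Open chromatin was profiled by ATAC-seq, in which a transposase cuts and tags accessible DNA, in PB3, a mouse breast cancer line labelled negative for Er, Pr and Her2. The untreated parental line was set beside 3 derivatives selected for resistance to eribulin, paclitaxel or vinorelbine, drugs that act on microtubules. Selection used 300, 500 and 800 nM of each drug. The series asks whether treatment can shift breast cancer cells from a mesenchymal toward an epithelial state through their chromatin. Each line had 2 libraries. Nothing in the labels says that these came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Libraries held 15644934 and 14173295 counts for PB3-Parental, 13419873 and 10521964 for PB3-ERI-R, 15029435 and 13774822 for PB3-PAC-R, and 24052237 and 23206697 for PB3-VIN-R. Line values are given as the mean ± SD of n = 2 libraries, and log2 fold changes as the estimate ± SE.

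PB3-ERI-R stood apart from the other lines. Across regions, the correlation between the 2 libraries of a line was 0.968 to 0.977. Libraries of PB3-Parental, PB3-PAC-R and PB3-VIN-R correlated with each other at 0.948 to 0.982, and those of PB3-ERI-R with the rest at 0.133 to 0.230. The first principal component held 94.2% of the variance. The peak lists held 37619 peaks for PB3-Parental, 30778 for PB3-ERI-R, 39414 for PB3-PAC-R and 45415 for PB3-VIN-R. A parental peak overlapped 63.51% of PB3-ERI-R peaks (95% interval 62.97 to 64.05), 88.01% of PB3-PAC-R peaks and 78.66% of PB3-VIN-R peaks. In base pairs, the Jaccard index against the parental list was 0.393, 0.795 and 0.748. Of the 57417 consensus regions, 18043 (31.42%) were peaks in every line, 15470 (26.94%) in every line but PB3-ERI-R, and 9700 (16.89%) in PB3-ERI-R alone. Within gene bodies lay 39.19% of regions, and 21.59% lay within 1 kb of a gene end.

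In PB3-ERI-R against PB3-Parental, most measured loci of epithelial genes gained accessibility and 21 of 35 mesenchymal loci lost it, although no shift of these lists passed camera with an estimated correlation (adjusted p = 0.788 for both epithelial lists and 0.994 for the mesenchymal one). Epcam, an epithelial adhesion molecule, rose from 42.1 ± 8.67 to 171 ± 5.33 CPM (log2 2.02 ± 0.14, edgeR adjusted p = 6.57e-07). Ehf, an epithelial transcription factor, rose from 6.0 ± 0.928 to 329 ± 33.9 CPM (log2 5.77 ± 0.16, adjusted p = 1.31e-08). Zeb1, a repressor of epithelial genes, fell from 127 ± 1.56 to 61.0 ± 1.85 CPM (log2 -1.05 ± 0.12, adjusted p = 2.85e-05). Lox, which crosslinks collagen, fell from 29.2 ± 8.37 to 1.75 ± 0.584 CPM (log2 -4.07 ± 0.30, adjusted p = 1.01e-06).

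These changes were part of a difference that covered most regions. Of 57415 tested regions, 41920 (73.01%) changed, 20338 gained and 21582 lost, and 32744 of them changed by at least 1 on the log2 scale. The median absolute log2 fold change of called regions was 2.24. Of 14939 gene loci, 8715 (58.34%) changed, 4186 up and 4529 down. The median log2 fold change over all regions was 0.07, and -0.29 without a scaling factor, where the split of calls became 14862 gained and 25149 lost. With loess offsets the median was 0.13 and the split 21754 to 19477. No left-out library moved the counts of regions or loci by more than 1.5 times.

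**Figure D1:**
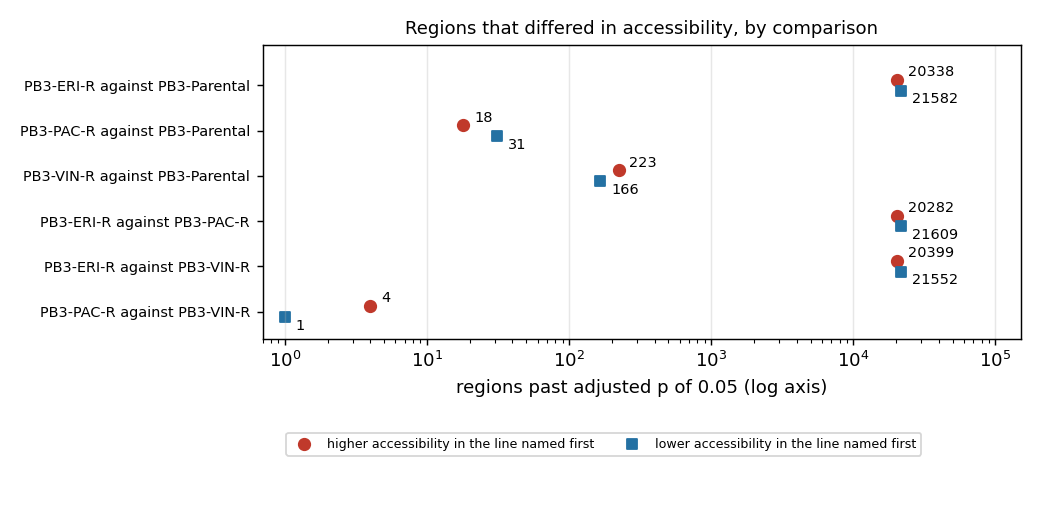
Number of regions (log axis) called gained or lost at an adjusted p under 0.05 in each comparison of lines, 2 libraries per line. Against the parental line, points stand at 20338 gained and 21582 lost for PB3-ERI-R, 18 and 31 for PB3-PAC-R, and 223 and 166 for PB3-VIN-R.

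Of the 28 measured loci of epithelial adhesion and keratin genes, 23 rose in PB3-ERI-R and the other 5 did not pass the test, with a median log2 fold change of 1.34. The counts were the same adjusted over the list alone and under each of the 4 other scalings. Camera gave an adjusted p = 1.84e-06 for the list and fry 0.00175, against an adjusted p = 0.788 with an estimated correlation. Cdh1, the E-cadherin gene, rose from 109 ± 19.3 to 219 ± 24.4 CPM (log2 1.01 ± 0.16, adjusted p = 0.000296). Dsp, a desmosome component, rose from 32.8 ± 5.47 to 208 ± 4.09 CPM, St14, a membrane protease of epithelia, by 2.84 ± 0.14 and Llgl2, a polarity gene, by 2.36 ± 0.12 on the log2 scale (1.23 with copy number offsets). Among epithelial transcription and splicing factors, 15 of 19 loci rose and 3 fell, the same counts as adjusted over the list alone (median 2.60, camera adjusted p = 0.000262, fry adjusted p = 0.000246, camera adjusted p = 0.788 with an estimated correlation). Esrp1, an epithelial splicing factor, rose from 7.71 ± 1.59 to 169 ± 2.84 CPM, and Elf5, a mammary transcription factor, rose by 5.32 ± 0.21 on the log2 scale.

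Among mesenchymal and extracellular matrix genes, 21 of 35 loci fell and 3 rose (21 and 4 adjusted over the list alone), with a median of -0.95. Camera gave an adjusted p = 0.00427 for this list and fry 0.0191, against an adjusted p = 0.994 with an estimated correlation. Axl, a receptor tyrosine kinase, fell from 129 ± 20.2 to 29.2 ± 0.494 CPM. Vim, the vimentin gene, fell from 193 ± 20.3 to 123 ± 1.06 CPM (log2 -0.65 ± 0.13, adjusted p = 0.00128, and -0.41 with copy number offsets). Ncam1, a neural adhesion molecule, changed by -1.32 ± 0.10, although its region at a gene end alone gave -0.15 (adjusted p = 0.511). EMT transcription factors moved both ways: 6 of 18 loci rose and 7 fell, also adjusted over the list alone (median 0.01, mean -0.09, camera adjusted p = 0.959), and with loess offsets 7 rose and 7 fell. Prrx1 fell by 1.92 ± 0.11 and Fosl1, an AP-1 member, fell by 2.16 ± 0.16 on the log2 scale, while Sox9 rose by 2.30 ± 0.14, or 1.44 with copy number offsets.

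**Figure D2:**
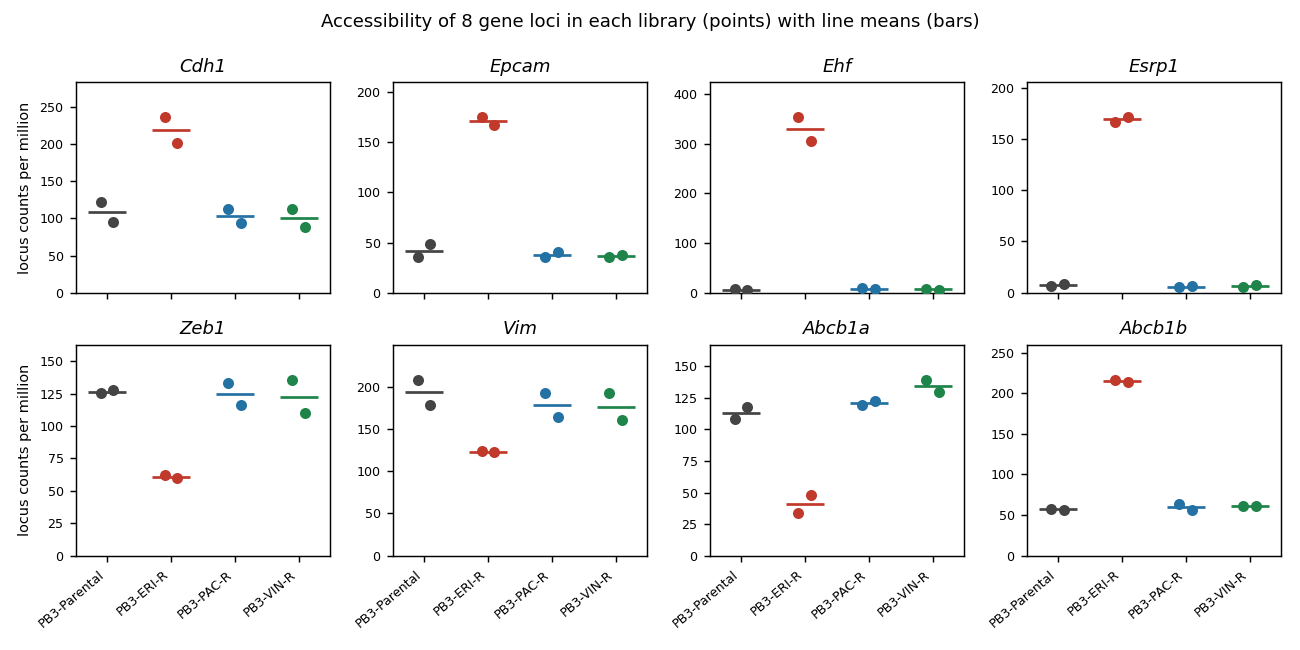
Normalised CPM at 8 gene loci in the 4 lines, with points for single libraries and bars for the mean of 2. Epcam stands at 42.1 in PB3-Parental and 171 in PB3-ERI-R, and Zeb1 at 127 and 61.0, while PB3-PAC-R (37.7 and 125) and PB3-VIN-R (36.7 and 123) lie near the parental values.

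Regions within 1 locus changed in opposite directions. The Cdh1 region at a gene end (chromosome 8, 106603127 to 106603867) rose from 4.22 ± 0.612 to 56.2 ± 3.68 CPM (log2 3.73, adjusted p = 6.12e-09), and of the 10 regions of the locus 6 were gained and 2 lost. The Vim region at a gene end (chromosome 2, 13573370 to 13574881) fell from 119 ± 16.8 to 3.69 ± 0.886 CPM (log2 -5.02, adjusted p = 7.44e-10). The Vim region inside the gene (13575941 to 13576414) rose from 11.7 ± 1.27 to 69.1 ± 1.15 CPM. All 5 regions of the Epcam locus were gained, and 5 of the 7 regions of Zeb1 were lost.

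The drug efflux and detoxification list was mixed in PB3-ERI-R, with 9 of 27 loci up and 16 down, also adjusted over the list alone (median -0.52, camera adjusted p = 0.498). Abcb1a and Abcb1b, neighbouring genes that encode the mouse P-glycoproteins, went apart. Abcb1a fell from 113 ± 7.06 to 40.9 ± 10.5 CPM (log2 -1.47 ± 0.15, adjusted p = 1.06e-05). Abcb1b rose from 57.0 ± 1.28 to 215 ± 1.35 CPM (log2 1.92 ± 0.10, adjusted p = 1.22e-07). Both lie at 5 to 10 Mb of chromosome 5, where the median region rose by 1.97, and with copy number offsets Abcb1a stood at -3.16 and Abcb1b at 0.22 (adjusted p = 0.105). Abcb4, a phospholipid transporter in the same window, rose by 2.96 ± 0.19, or 1.28 with these offsets, and Abca3, a lipid transporter, fell by 3.43 ± 0.19.

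Tubulins and microtubule-associated proteins had 11 of 38 loci up and 9 down in PB3-ERI-R, also adjusted over the list alone (median 0.03, camera adjusted p = 0.907), and 10 up and 11 down without a scaling factor. Dcx, a microtubule-binding protein of migrating neurons, rose from 0.185 ± 0.0424 to 39.8 ± 1.47 CPM, and Map1b, a neuronal microtubule protein, fell from 144 ± 2.66 to 31.5 ± 3.99 CPM. Mapre3, which binds growing microtubule ends, rose by 2.49 ± 0.12, or 1.13 with copy number offsets. In the SWI/SNF list 6 of 26 loci rose and 9 fell, also adjusted over the list alone (camera adjusted p = 0.959), and 5 rose and 5 fell with copy number offsets. Arid2, a subunit of the PBAF form of the complex, fell from 56.1 ± 7.35 to 6.05 ± 0.429 CPM. Smarcd3 changed by 1.43 ± 0.13 and stood at 0.06 (adjusted p = 0.756) with copy number offsets. In the TGF-beta list 14 of 30 loci rose and 6 fell (15 and 8 adjusted over the list alone, camera adjusted p = 0.498). Tgfb2, a ligand, rose by 1.43 ± 0.11, Ski, an inhibitor of the pathway, fell by 1.37 ± 0.13 (log2 -0.57 with copy number offsets), and Smurf1 changed by 1.81 ± 0.11, or 0.23 (adjusted p = 0.0931) with copy number offsets. Mapre3, Smarcd3 and Smurf1 lie in parts of chromosome 5 where the median region rose by at least 1.

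In the mitotic list 12 of 29 loci rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 0.117). Birc5, the survivin gene, rose from 48.4 ± 2.87 to 131 ± 8.84 CPM, Bub1b, a checkpoint kinase, by 1.22 ± 0.13, and Cenpa, a centromeric histone on chromosome 5, by 1.75 ± 0.11. With copy number offsets Birc5 stood at 0.30 (adjusted p = 0.037) and Cenpa at 0.39 (adjusted p = 0.0118). Birc5, Llgl2 and Sox9 lie at 110 to 120 Mb of chromosome 11, where the windows had medians of 1.2 and 1.42. In the interferon list 6 of 21 loci rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.498), with Rsad2 up by 3.50 ± 0.44 and Oas1a by 5.16 ± 0.68. Apoptosis regulators had 9 of 28 up and 12 down, also adjusted over the list alone (camera adjusted p = 0.907), and 8 up and 7 down with copy number offsets. Bik, a promoter of apoptosis, rose by 2.80 ± 0.20 and Pmaip1, another, fell by 1.73 ± 0.15. The AP-1 family had 4 of 15 up and 3 down, also adjusted over the list alone (median -0.02, mean -0.11, camera direction up, adjusted p = 0.959), and 3 up and 4 down with copy number offsets. Mafg rose by 1.27 ± 0.12. Of the housekeeping genes 2 of 15 rose and 1 fell, also adjusted over the list alone (median 0.05, camera adjusted p = 0.907), but 0 rose and 2 fell with copy number offsets. Actb stood at 0.66 ± 0.12, Pgk1 at 0.86 ± 0.11 and Tbp at -0.86 ± 0.15, and the first pair turned to -0.93 and -0.05 with those offsets. Tbp stood at -0.13 (adjusted p = 0.552) within 1 kb of a gene end.

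Markers of mammary and other cell types also moved in both directions in PB3-ERI-R. The counts given for these lists were the same adjusted over the list alone. Mammary basal markers had 7 of 16 loci up and 3 down (camera adjusted p = 0.54), with Krt14 rising from 11.2 ± 2.85 to 129 ± 17.6 CPM, Krt5 rising by 3.46 ± 0.26 and Vcam1 falling from 44.9 ± 7.93 to 2.36 ± 1.57 CPM. Mammary luminal markers had 8 of 18 up and 5 down (camera adjusted p = 0.498), and Prlr, the prolactin receptor gene, rose from 1.19 ± 0.0389 to 141 ± 4.65 CPM. Of 9 macrophage markers, 5 fell and 2 rose (median -2.17, camera adjusted p = 0.332). Among them Mrc1 fell from 49.0 ± 1.21 to 4.82 ± 0.999 CPM and Csf1r from 17.0 ± 1.06 to 3.77 ± 0.0255 CPM. Neural markers had 5 of 14 up and 9 down (median -0.78, mean 0.21, camera adjusted p = 0.683), and Sox11 rose from 0.334 ± 0.0339 to 81.1 ± 3.23 CPM. Endothelial markers had 6 of 12 up and 4 down (median 0.11, mean -0.23, camera adjusted p = 0.907), with Kdr falling by 3.35 ± 0.22 and Flt1, near an end of chromosome 5, rising by 2.04 ± 0.12, or 0.51 with copy number offsets. Of 7 adipocyte markers 2 rose and 3 fell (median 0.10, mean -0.40, camera adjusted p = 0.907), with Pparg falling by 2.28 ± 0.12.

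**Figure D3:**
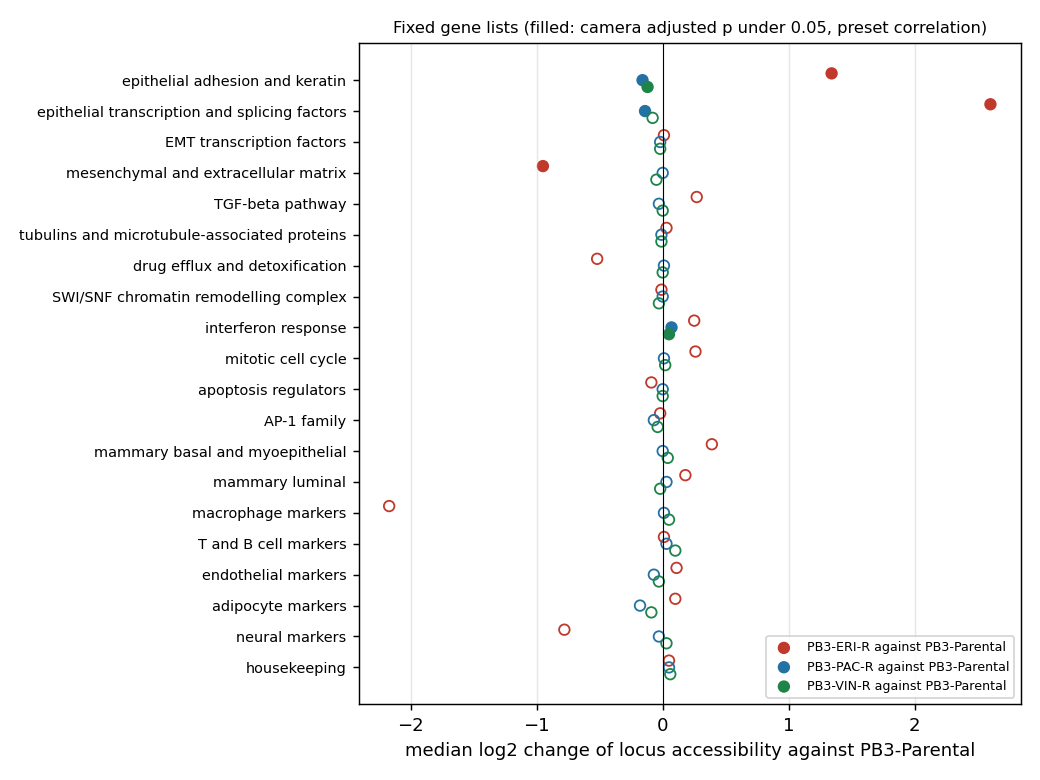
Median log2 fold change against the parental line of each of the 20 fixed gene lists, 1 point per list and resistant line, filled where camera with a preset correlation gave an adjusted p under 0.05. In PB3-ERI-R the epithelial transcription and splicing factors stand at 2.60, the epithelial adhesion list at 1.34 and the mesenchymal list at -0.95.

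Regions with signal in PB3-ERI-R and no parental counts included Cdkn2b and Cdkn2a, which encode inhibitors of cyclin-dependent kinases. The Cdkn2b region at a gene end (chromosome 4, 89310517 to 89311248) held 1071 counts in PB3-ERI-R and 0 in PB3-Parental, at least 567.8-fold higher (adjusted p = 6.06e-09). A region 36.6 kb from Mtap (89217739 to 89218438), a gene of methionine salvage, was at least 492.0-fold higher, and the Cdkn2a region (89294304 to 89294954) at least 338.3-fold higher. Regions in Ano4 on chromosome 10 (891 counts) and Luzp2 on chromosome 7 (749 counts) were at least 475.1 and 394.2-fold higher. Regions with parental signal and 0 counts in PB3-ERI-R lay at Nkain3 (chromosome 4, at least 76.4-fold lower), Galnt14 (chromosome 17, 72.9), Aldoart1 (chromosome 4, 68.5), Erc2 (chromosome 14, 61.5) and Rims2 (chromosome 15, 45.7).

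The longest run of consecutive regions without parental counts, singled out after its values were seen, spanned Cdkn2a and Cdkn2b. Its 5 regions cover 143 kb of chromosome 4 (89217739 to 89360718). They held 3296 counts in PB3-ERI-R (1849 and 1447 per library), 0 in PB3-Parental, 1 in PB3-PAC-R and 0 in PB3-VIN-R. In PB3-VIN-R the stretch with almost no signal was longer, with 2 counts over 21 regions (89128152 to 91376744) that held 274 counts in PB3-Parental, 213 in PB3-PAC-R and 12741 in PB3-ERI-R.

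**Figure D4:**
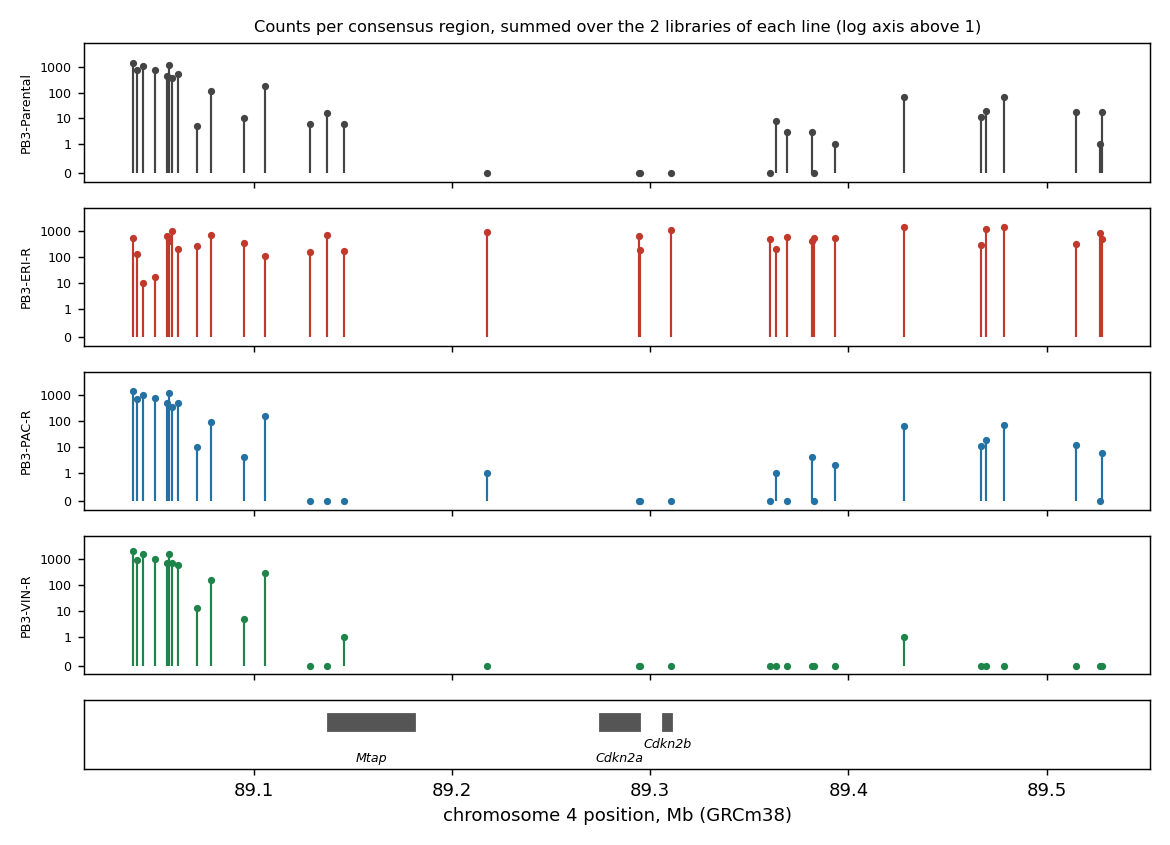
Counts per consensus region, summed over the 2 libraries of each line, along chromosome 4 around Cdkn2a and Cdkn2b, with gene bodies drawn to scale. The 5 regions from 89217739 to 89360718 hold 3296 counts in PB3-ERI-R, 1 in PB3-PAC-R and 0 in the other lines.

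Changed regions of PB3-ERI-R lay near gene ends less often than unchanged ones. Within 1 kb of a gene end lay 26.68% of gained and 6.30% of lost regions, against 36.22% of uncalled regions (odds ratios 0.641 and 0.118, Fisher's exact test, adjusted p = 7.75e-83 for gained regions). Here and for the other lines, Fisher's exact test treats regions as replicates, so its p-values describe only these regions and not a spread between cultures.

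In PB3-PAC-R against PB3-Parental few regions changed in the main fit, which has no replicate block, and none of the epithelial or mesenchymal genes named beforehand passed the test. Pax6, a transcription factor of eye and neural development, fell from 15.7 ± 1.88 to 1.41 ± 0.0930 CPM (log2 -3.47 ± 0.34, edgeR adjusted p = 0.00469). C130074G19Rik fell from 16.7 ± 0.568 to 1.18 ± 0.00362 CPM (log2 -3.82 ± 0.30, adjusted p = 0.00173). Setbp1, a DNA-binding protein gene, rose from 5.60 ± 2.11 to 25.9 ± 1.70 CPM (adjusted p = 0.0153). Cdh1 stood at -0.08 ± 0.16, Epcam at -0.16 ± 0.14, Zeb1 at -0.02 ± 0.12, Vim at -0.12 ± 0.13, Abcb1a at 0.10 ± 0.14 and Abcb1b at 0.06 ± 0.10, each with an adjusted p of 1.00.

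Of 57415 regions 49 changed in PB3-PAC-R, 18 gained and 31 lost, and 3316 had an unadjusted p under 0.05. Of the loci 17 changed, 4 up and 13 down, and 844 had an unadjusted p under 0.05. The DESeq2 test called 154 regions and 102 loci. A replicate block gave many more of both, as listed under processing, although the labels pair libraries by number only. Gained regions lay in Ext1 (chromosome 15, log2 2.63, adjusted p = 0.00833), Setbp1 (chromosome 18, 2.47) and Endou (chromosome 15, 364 counts against 88), and near Slco1a1 (chromosome 6, 2.58) and Hlx (chromosome 1, 2.11). Lost regions lay at C130074G19Rik (chromosome 1, -3.81, adjusted p = 0.000349), Pax6 (chromosome 2, -3.47), Shroom3 (chromosome 5, -2.59), Grm8 (chromosome 6, -2.46) and Rbms3 (chromosome 9, -2.41). None of the 18 gained regions lay within 1 kb of a gene end, against 21.59% of uncalled regions (Fisher's exact test, adjusted p = 0.0297, 0.0866 within 2 kb and 0.242 stratified by abundance). Of lost regions 38.71% did (odds ratio 2.29, adjusted p = 0.0336), with odds ratios of 1.84 (adjusted p = 0.12) within 2 kb and 3.95 (adjusted p = 0.0018) stratified by abundance.

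Among the 20 lists, epithelial adhesion genes were shifted down in PB3-PAC-R (median -0.16, camera adjusted p = 0.000448, fry adjusted p = 0.255, camera adjusted p = 0.885 with an estimated correlation). In edgeR 0 of 28 loci passed, 6 fell at an unadjusted p under 0.05, and 1 fell adjusted over the list alone and by DESeq2. Epithelial transcription and splicing factors were shifted down (median -0.14, camera adjusted p = 0.00138, fry adjusted p = 0.122, camera adjusted p = 0.788 with an estimated correlation). In edgeR 0 of 19 passed, 4 fell and 1 rose at an unadjusted p under 0.05, and DESeq2 called 0. Interferon genes were shifted up (median 0.07, mean 0.36, camera adjusted p = 0.00116, fry adjusted p = 0.266, camera adjusted p = 0.788 with an estimated correlation; adjusted p = 0.0967 without PB3-PAC-R replicate 2). In edgeR 0 of 21 passed, 3 rose at an unadjusted p under 0.05, and 2 rose adjusted over the list alone and by DESeq2. Pax6, a neural marker, was the single list locus past the edgeR test. Adjusted over the list alone, 1 drug efflux and 1 endothelial locus also rose. The other 17 lists had camera adjusted p from 0.336 to 0.984, and among them the macrophage list differed in sign between median (0.01) and mean (-0.05).

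The counts for PB3-PAC-R rest on single libraries. Regions numbered 172 without parental replicate 1, 16 without parental replicate 2, 3 without either PB3-ERI-R library, 17 and 11 without PB3-PAC-R replicate 1 and 2, and 26 without either PB3-VIN-R library. Loci numbered 5 without parental replicate 2, 8 without either PB3-ERI-R library, and 9 and 6 without PB3-PAC-R replicate 1 and 2. The regions at C130074G19Rik and Pax6 passed in each of these fits, and the other 8 named regions missed the threshold without either PB3-ERI-R library (adjusted p 0.0559 to 0.157). With copy number offsets 26 regions were called. The named regions at Slco1a1 (2.35), Setbp1 (2.34), Hlx (2.25), Endou (1.84) and Rbms3 (-2.29) then missed the threshold (adjusted p 0.0524 to 0.118).

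In PB3-VIN-R against PB3-Parental 389 regions changed, against 49 in PB3-PAC-R, an order that turned without PB3-VIN-R replicate 2 (14 against 26). With all libraries thinned to the smallest total the counts were 311 and 61. Cdh1, Epcam, Zeb1 and Vim again did not pass the test. Endou, an endoribonuclease gene, rose from 30.6 ± 8.03 to 92.2 ± 0.701 CPM (log2 1.59 ± 0.16, edgeR adjusted p = 0.00563). Fgf13, a growth factor homologue on the X chromosome, rose from 69.2 ± 0.130 to 139 ± 3.47 CPM (log2 1.01 ± 0.10, adjusted p = 0.00563). It lies at 55 to 60 Mb, where the median region rose by 0.71, so much of its rise is shared with its surroundings. Ranbp17, a nuclear transport receptor, fell from 35.7 ± 0.583 to 11.5 ± 0.793 CPM (log2 -1.64 ± 0.15, adjusted p = 0.00563). Cdh1 stood at -0.11 ± 0.16, Epcam at -0.20 ± 0.14, Zeb1 at -0.04 ± 0.12, Vim at -0.13 ± 0.13 and Abcb1b at 0.10 ± 0.10, each with an adjusted p of 1.00, and Abcb1a at 0.25 ± 0.14 (adjusted p = 0.908).

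In total 389 regions changed in PB3-VIN-R, 223 gained and 166 lost, and 5667 had an unadjusted p under 0.05. The DESeq2 test called 290 gained and 338 lost, and a replicate block gave many more regions, as listed under processing. Of the loci 100 changed, 59 up and 41 down, and 1064 had an unadjusted p under 0.05. Of the 59 risen loci 20 lie on the X chromosome, where the windows from 35 to 60 Mb had medians of 0.61 to 0.71. Gained regions lay near Slco1a1, an organic anion transporter gene (chromosome 6, log2 3.43, adjusted p = 0.00373), and Slc13a1 (chromosome 6, 3.06), and in Galc (chromosome 12, 3.03), Col25a1 (chromosome 3, 2.84) and Spata16 (chromosome 3, 2.73). Lost regions lay in Elavl2 (chromosome 4, 0 counts against 24, at least 12.4-fold lower) and at Mtap (chromosome 4, 0 counts against 16, at least 8.2-fold lower), both in the stretch of 21 regions with 2 counts, and at Bcas3 (chromosome 11, log2 -2.67), Stpg2 (chromosome 3, -2.59) and Reep3 (chromosome 10, -2.46). Within 1 kb of a gene end lay 6.28% of gained regions against 21.65% of uncalled ones (odds ratio 0.242, Fisher's exact test, adjusted p = 9.34e-10, or 0.131 stratified by abundance). For lost regions the share was 23.49% (odds ratio 1.11, adjusted p = 0.571, or 1.77 with 0.00299 stratified by abundance).

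Epithelial adhesion genes were shifted down in PB3-VIN-R (median -0.12, camera adjusted p = 0.00138, fry adjusted p = 0.266, camera adjusted p = 0.885 with an estimated correlation), and of 28 loci 1 fell, also adjusted over the list alone. That locus was Myo5b, a motor of epithelial membrane traffic, which fell from 101 ± 2.99 to 58.9 ± 1.85 CPM (log2 -0.78 ± 0.10, adjusted p = 0.017). Interferon genes were shifted up (median 0.05, mean 0.33, camera adjusted p = 0.0414, fry adjusted p = 0.427, camera adjusted p = 0.885 with an estimated correlation). In edgeR 0 of 21 passed, 4 rose and 1 fell at an unadjusted p under 0.05, and 3 rose adjusted over the list alone and by DESeq2. Slco1a5, in the drug efflux list, stood at 1.16 ± 0.18 (adjusted p = 0.0236) and Xiap, an inhibitor of apoptosis on the X chromosome, at 0.65 ± 0.11 (adjusted p = 0.0291). With copy number offsets they stood at 0.77 (adjusted p = 0.149) and 0.57 (adjusted p = 0.105). The window of Xiap, with 4 loci, took the offset of the whole chromosome, while its regions had a median of 0.61. Pax6 fell by 1.93 ± 0.28 on the log2 scale. No other list locus passed the edgeR test, and the other 18 lists had camera adjusted p from 0.113 to 0.984. Median and mean differed in sign for neural markers (0.03 and -0.09) and mammary luminal markers (-0.02 and 0.11). Adjusted over the list alone, 2 mammary basal loci and 1 housekeeping locus rose and 1 drug efflux locus fell.

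The counts for PB3-VIN-R also rest on single libraries. Regions numbered 991 without parental replicate 1, 52 without parental replicate 2, 118 and 120 without PB3-ERI-R replicate 1 and 2, 604 without PB3-PAC-R replicate 2, and 52 and 14 without PB3-VIN-R replicate 1 and 2. With copy number offsets 219 regions were called, and those at Elavl2 and Mtap missed the threshold (adjusted p = 0.053 and 0.0876). Loci numbered 6 without parental replicate 2, 54 and 62 without PB3-ERI-R replicate 1 and 2, and 60 and 14 without PB3-VIN-R replicate 1 and 2. Without PB3-VIN-R replicate 2 the epithelial adhesion list gave an adjusted p = 0.335, and Myo5b, Pax6, Slco1a5 and Xiap gave adjusted p of 0.0891, 0.0827, 0.131 and 0.0784. Without parental replicate 2 these 4 loci gave 0.116, 0.137, 0.214 and 0.3. The regions near Slco1a1, in Galc and in Reep3 passed whichever library was left out, and the other 7 named regions missed the threshold without PB3-VIN-R replicate 2 (adjusted p 0.118 to 0.319). The interferon list missed the threshold without any of 7 libraries (adjusted p 0.0515 to 0.271) and passed without parental replicate 2. The mesenchymal list passed without PB3-VIN-R replicate 1 (adjusted p = 0.0283), and the mammary basal and macrophage lists passed without PB3-VIN-R replicate 2 (adjusted p = 0.0433 for each).

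Comparisons between resistant lines set PB3-ERI-R apart from both others. It differed from PB3-PAC-R at 41891 regions (20282 gained, 21609 lost) and from PB3-VIN-R at 41951 (20399 gained, 21552 lost). A total of 38971 regions differed in the same direction from the parental line and both other resistant lines, 18595 gained and 20376 lost. Against PB3-PAC-R, regions at Cdkn2b, Mtap and Dlg2 were at least 552.9, 352.0 and 349.0-fold higher, and regions at Nkain3, Aldoart1 and Galnt14 at least 78.1, 66.1 and 58.3-fold lower. Against PB3-VIN-R, regions at Cdkn2b, Mtap and Cdkn2a were at least 901.7, 781.4 and 537.2-fold higher, and regions at Nkain3, Galnt14 and Aldoart1 at least 88.3, 65.6 and 51.3-fold lower.

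PB3-PAC-R and PB3-VIN-R differed from each other at 5 regions by edgeR, while 2491 had an unadjusted p under 0.05 and the DESeq2 test called 54. More were also called with a replicate block, as listed under processing. PB3-PAC-R was higher at F8 on the X chromosome (log2 2.59, adjusted p = 0.0422) and Zfp882 on chromosome 8 (1.69, adjusted p = 0.0422), and lower in Hs6st2 on the X chromosome (-2.75, adjusted p = 0.00561). The other 2 regions, outside the naming rule and named after their values were seen, lie on chromosome 4 at 89427797 to 89428483 and 89478727 to 89479515, more than 50 kb beyond Cdkn2b, within the stretch without PB3-VIN-R signal (adjusted p = 0.00561 for each). The count was 0 without either PB3-ERI-R library or either PB3-VIN-R library, 2 without PB3-PAC-R replicate 2, 33 without either parental library, and 0 with copy number offsets.

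PB3-PAC-R and PB3-VIN-R shared more changes than independent calls would give, although part of the overlap can come from the parental libraries they are both compared with. Both gained 17 regions and both lost 16, where independent calls would give 0.07 and 0.09, and 0 regions were called in opposite directions. The values for independent calls do not allow for the shared parental libraries. Simulated unchanged lines gave 0 and 0.05, but lines without changes yield almost no calls. They thus do not measure how much of the overlap comes from these libraries. Among the shared changes, Ranbp17, Pax6 and C130074G19Rik lost and Setbp1, Endou and Slco1a1 gained regions in both lines, as singled out after their values were seen. With the PB3-ERI-R libraries left out of the fit, only 2 regions were called in PB3-PAC-R at all. At most 2 of the 33 shared regions could then be called in both lines, so the shared count depends on the fit. With copy number offsets 14 of the 33 shared regions were still called in both lines. Those in Endou, near Slco1a1 and inside Setbp1 were not among them, although the median absolute log2 fold change of the 33 went from 2.11 to 2.13 in PB3-PAC-R and from 1.96 to 1.99 in PB3-VIN-R. The log2 fold changes of these lines correlated at r = 0.65 across all regions, against a mean of 0.51 in simulated unchanged lines that share the 2 parental libraries, and the covariance was 0.111 against 0.043. When each line was compared with a different parental library, the covariance was 0.0135 and 0.0432 for the 2 assignments, against simulated values of -0.000737 to 0.000703. The simulated libraries were drawn independently, with no effect of replicate number and no shift over large stretches. In the data, deviations of libraries with the same number correlated at 0.36 to 0.45 among these 3 lines. The simulations thus cannot show what such effects alone would give. The correlation of fold changes between PB3-PAC-R and PB3-VIN-R was 0.82 without parental replicate 1 and 0.48 without PB3-PAC-R replicate 1. Both lines also had raised medians over large stretches. Chromosome 15 stood at 0.22 in PB3-PAC-R and 0.11 in PB3-VIN-R. Windows from 110 to 150 Mb of chromosome 6 stood at 0.22 to 0.28 and 0.25 to 0.34. Of the 33 shared regions, 4 lie on chromosome 15 and 2 on chromosome 6. Correlation and covariance were not recomputed with copy number offsets, so the part of these shifts was not tested. For PB3-ERI-R the covariance was -0.009 with PB3-PAC-R and -0.115 with PB3-VIN-R, against 0.043 for simulated unchanged lines. The correlation was -0.01 and -0.10, the latter 0.01 and 0.05 without parental replicate 1 and 2. PB3-ERI-R and PB3-PAC-R both gained 7 regions (6.38 if independent) and both lost 16 (11.65), with 20 in opposite directions. PB3-ERI-R and PB3-VIN-R both gained 66 (78.99) and both lost 47 (62.4), with 192 in opposite directions.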

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

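In this part, the thinning test for PB3-ERI-R and the tests around Cdkn2a were chosen only after the result was seen, as was the use of the planned scaling and copy number fits as tests. Resistant lines differed from each other by edgeR, and since the parental term cancels, a test of whether their changes against the parental line differ is this same comparison and does not test resistance as the cause. Regions that differed numbered 41891 between PB3-ERI-R and PB3-PAC-R, 41951 between PB3-ERI-R and PB3-VIN-R, and 5 between PB3-PAC-R and PB3-VIN-R.

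PB3-ERI-R differed from the parental line at most regions, 41920 of 57415. With every library thinned to the smallest total, 41868 regions changed, which argues against library depth. The lowest count under 3 other scalings was 40011, and removing the median of each 5 Mb window left 40161, which argues against scaling and against DNA copy number over large windows as the whole cause. The 3 regions on the Y chromosome rose by a median of 4.74 on the log2 scale (2426 counts against 146 in PB3-Parental) and those on the X chromosome by 0.69, but 3 regions with counts in each line are too few to settle where the cells came from. A change of cell state under eribulin selection stays a candidate explanation, as do a rare subclone of the parental culture and cells of another origin under this label. Both libraries of the line differ from the rest alike, which does not separate these. If the DNA around Cdkn2a is missing in the other lines, as weighed below, a change of state alone would not explain the signal there.

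Around Cdkn2a and Cdkn2b, a block of 5 regions was chosen by its lack of parental counts, so it was tested in the 4 libraries of PB3-PAC-R and PB3-VIN-R, which held 1 count (exact Poisson upper bound 5.57). Over 9592 other runs of 5 regions that are peaks in PB3-ERI-R alone, these libraries held at least 19 counts, with a median of 731. So few counts were thus not seen at other regions of this kind. Those runs could skip regions in between and were not chosen for low parental counts. Both lines resemble the parental line, so the comparison is not independent of the choice and does not exclude closed chromatin with the DNA present. A count of 1 is as would be seen if the DNA of the block is missing in most cells of the 3 lines, and since cells cannot regain missing DNA, cells like PB3-ERI-R would then predate the loss. The longest run chosen by 0 counts in PB3-PAC-R and PB3-VIN-R, 4 regions, held 0 parental counts, which allows at most 0.0794% of such signal for counting error only. The 10 regions chosen by at most 1 count each held 39 parental counts, or 0.481% of the PB3-ERI-R signal there after scaling. All 39 lie outside the block of 5 regions, and 16 of them, at a gene end of Mtap, split 13 and 3 between the parental libraries. They were thus not spread as the PB3-ERI-R signal was and do not measure a share of such cells. A rare subclone of the parental culture that eribulin selected and cells of another origin or a mislabelled sample cannot be told apart, because parental counts this low leave room for both.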

How the results depend on the processing

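The fits that thinned the libraries, left out PB3-ERI-R, or did so with a replicate block were added after seeing the data. Counts for PB3-ERI-R held within 1.5 times under each setting run, except that its loci numbered 4370 when restricted to regions within 1 kb of a gene end and 4297 with a log2 change of at least 1. Leaving out single libraries gave 37899 to 42164 regions against the parental line, 38162 to 42070 against PB3-PAC-R, 38283 to 41894 against PB3-VIN-R, and 35214 to 38016 regions specific to PB3-ERI-R. Of the 60 tests of lists, 8 passed with the preset correlation and 0 with an estimated one, and 6 to 8 passed with single libraries left out.

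Of the regions changed in PB3-PAC-R against PB3-Parental, 49 became 32 without a scaling factor, 26 with copy number offsets, 154 with the DESeq2 test, 2 in a fit of only the lines compared, 2 with the PB3-ERI-R libraries left out and 7 at an adjusted p under 0.01. They numbered 3 to 172 with single libraries left out. In PB3-VIN-R against PB3-Parental, 389 became 246 with loess offsets, 219 with copy number offsets, 628 with DESeq2, 197 with only the lines compared, 110 with PB3-ERI-R left out, 53 at an adjusted p under 0.01, and 14 to 991 with single libraries left out. In PB3-PAC-R against PB3-VIN-R, 5 became 3 with DESeq2 size factors, no scaling factor, loess offsets, a mean CPM of at least 2 or an adjusted p under 0.01. There were 0 with copy number offsets, only the lines compared or PB3-ERI-R left out, 54 with DESeq2, and 0 to 33 with single libraries left out. Changed loci in PB3-PAC-R went from 17 to 102 with DESeq2, 2 with only the lines compared, 9 with PB3-ERI-R left out, 10 near gene ends, and 5 to 23 with single libraries left out. Changed loci in PB3-VIN-R went from 100 to 218 with DESeq2, 52 with PB3-ERI-R left out, 21 near gene ends, and 6 to 99 with single libraries left out. Fits with fewer libraries have fewer degrees of freedom, and for the other settings the cause was not tested.

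The labels pair libraries by replicate number only. Deviations of libraries with the same number correlated at 0.07 to 0.45 over the 6 pairs of lines, with 2 pairs of libraries in each. On the second principal component, which held 1.8% of the variance, replicate 1 stood above replicate 2 in every line. With a replicate block, 45214 regions changed in PB3-ERI-R, 636 in PB3-PAC-R, 2717 in PB3-VIN-R and 226 between PB3-PAC-R and PB3-VIN-R, and 162 loci in PB3-PAC-R and 464 in PB3-VIN-R. The interferon list in PB3-VIN-R gave an adjusted p = 0.149 with the block. With the block and PB3-ERI-R left out these were 917, 3667 and 333 regions, and 259 and 598 loci. The cause was not tested.

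The correlation of fold changes between PB3-ERI-R and PB3-VIN-R, -0.10, was -0.07 with loess offsets and -0.12 to 0.05 with single libraries left out, turning to 0.01 and 0.05 without parental replicate 1 and 2. It ran from -0.12 to 0.15 for PB3-ERI-R and PB3-PAC-R and from 0.48 to 0.82 for PB3-PAC-R and PB3-VIN-R. The odds ratio near gene ends for regions gained in PB3-PAC-R was 0.172 within 2 kb and 0 stratified by abundance, and for lost regions 1.84 within 2 kb, all past the threshold no longer. In PB3-VIN-R the stratified odds ratio was 0.618 for gained regions, past the threshold no longer, and 1.77 for lost regions, now past it. Overlap with parental peaks was 61.56, 89.14 and 79.74% for PB3-ERI-R, PB3-PAC-R and PB3-VIN-R in the upper part of each list by q, and 58.14, 91.97 and 90.28% with equal numbers of top peaks. The cause was not tested.

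Of the results for named loci, regions and lists, 3023 kept their side of the threshold, 203 missed the threshold and 3 newly passed. Another 2 turned direction while past the threshold in at least 1 of the compared fits. The 3023 include results that missed the threshold in both fits, and among those a change of direction was not counted. Those 2 were Actb (-0.93) and Pgk1 (-0.05) in PB3-ERI-R with copy number offsets, which remove the median of the surrounding window. In simulated data changes of 1 on the log2 scale were recovered in 36 to 52% of regions and 90 to 96% of loci. Corrections for GC content, alone or with the replicate block, and the motif tests were not run, and distances to transcription starts were replaced by distances to gene bodies.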

Other observations

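In this part, all tests on chromosome 5 were chosen after the windows had been noticed, and the genes listed first after their values were seen.

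Some loci in PB3-ERI-R gained or lost many regions at once. Among gains, Auts2, a neurodevelopmental gene, gained 20 of its 24 regions (locus log2 fold change 5.39), and Fry, a gene of cell morphogenesis, gained 15 of 15 (4.54). Fry lies at 150 to 155 Mb of chromosome 5, where the median region rose by 3.14. Among losses, Lpp, a focal adhesion gene, lost 28 of 32 regions (-1.21), Tenm3, a teneurin, lost 23 of 27 (-2.24), Rere, a nuclear receptor coregulator, lost 20 of 23 (-1.65) and Plxna2, a semaphorin receptor, lost 16 of 19 (-1.78).

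Both ends of chromosome 5 were more accessible in PB3-ERI-R, with medians of 1.16 to 3.14 on the log2 scale in 11 windows of 5 Mb, from 5 to 45 Mb except 25 to 30, and from 135 to 155 Mb. Windows with a median of at least 1 were chosen by every other region along the chromosome (11 windows, from 0 to 45 Mb except 10 to 15 and 25 to 30, and from 135 to 155 Mb), and the 1837 regions in between were tested. Neighbouring regions share the shift of their window, so this choice largely fixed the direction of the result at gene ends. The permutation p-values treat regions of 1 line as replicates and describe only these regions. Regions near gene ends that were peaks in every line had a median of 1.78 in these windows (145 regions) and 0.35 between 45 and 135 Mb (138 regions), a difference of 1.43 (two-sided permutation p = 2e-05, the smallest that 100000 resamples can give). Regions closed in PB3-ERI-R held 180 of its counts per kb in the windows and 103 in the middle, a ratio of 1.75 (permutation p = 0.00694), against 926 and 918 in the parental libraries. The rise was thus not confined to open regions, which argues against opening of single regulatory regions without extra DNA. It does not separate extra copies from opening across whole windows. Extra copies of both chromosome ends stay a candidate and may raise the values of Abcb1b, Abcb4, Mapre3, Cenpa, Smurf1 and other genes there. Whether such copies were gained under selection or present before it was not tested.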
